A study of Mus musculus with 6 samples.

How the data were processed

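Messenger RNA of whole kidney was measured by RNA sequencing in 6 libraries from male C57BL/6 mice, 8 weeks old, whose kidneys were taken after 14 days of unilateral ureteral obstruction (UUO). UUO is a surgical model in which tying off a ureter damages the tubules of that kidney and fills the tissue with scar matrix. There were 3 libraries from floxed mice, in which loxP sites flank part of the Abl1 gene and the gene is intact, and 3 from knockout mice that also carried Ksp-Cre. Ksp-Cre is a Cre recombinase under the promoter of kidney-specific cadherin (Cdh16), which is active in tubule epithelium. Groups and replicate numbers were taken from the sample titles, which name the first group as controls only. The genotype label of the controls reads WT, whereas the design text describes floxed mice, and floxed is used here. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these samples. No pair of libraries held identical values.

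The deposited table gives FPKM (fragments per kilobase of gene, relative to the mapped fragments of the library) per gene and library, made by the authors and rounded to 2 decimals, per the file headers and the values. It has 18849 genes with symbols and Entrez identifiers. The genome build was mm9, per the submitters' processing notes. The aligner, the counting tool, the annotation and any filter are not given in the sources used here. Total RNA was extracted with TRIzol and libraries were made with an Illumina protocol, per the labels' protocols. Strand use during counting is not given either, so reads of overlapping genes, antisense partners and near-identical family members (such as the Cyp4a genes) cannot be told apart in these values. FPKM is relative to all mapped fragments of a library, so a few abundant genes can move the values of the rest. The available RefSeq gene table belongs to another build than mm9 (GRCm38), and was used for names and gene neighbours only, with no coordinates printed. Of the Entrez identifiers, 18792 were found in that table, and 26 symbols that a spreadsheet had turned into dates were restored through it.

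The table carries no read totals. Low values of short genes fall near whole multiples of the value of 1 fragment, which allowed an estimate of the depth from transcripts of 300 to 2000 nucleotides. Between 63.2% and 66.3% of those low values lay within 0.2 of a whole number of fragments. With the transcript lengths shuffled among the same genes and the depth fitted anew, in 200 shuffles per library, that share was at most 51.8%. The estimate is approximate. It came to 16050000, 17800000 and 17850000 fragments for floxed replicates 1, 2 and 3, and to 17050000, 16200000 and 16000000 for knockout replicates 1, 2 and 3. At that depth 1 FPKM in a 2-kb transcript stands for about 32.0 to 35.7 fragments.

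Genes with FPKM of at least 1 in at least 3 of the 6 libraries were tested, 13390 in all. Values were converted to log2(FPKM + 1) and knockout was compared with floxed by limma 3.58.1 in R 4.3.3, with a mean-variance trend, group as the only term, two-sided tests and Benjamini-Hochberg adjustment at 0.05. All log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. For Abl1 an exact permutation test was added. With 3 against 3 libraries its smallest two-sided p is 0.1. Gene lists were tested with camera in limma, with a preset inter-gene correlation of 0.01, over the 45 of 48 lists that had at least 5 tested members. Camera compares a list with the remaining genes. It was repeated with the correlation estimated per list, and fry, which asks whether the genes of a list move on balance in one direction, was run beside it. For each list the members past 0.05 were counted after adjustment over all genes and after adjustment over the list alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 read the table and drew the plots.

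The lists hold 1149 distinct genes, of which 1116 were found in the table. They cover kidney cell types, matrix, Wnt, TGF-beta and PDGF signalling, mesenchymal transition, inflammation, metabolism, stress and tissue that could be carried along in dissection. The Wnt, mesenchymal transition and PDGF lists were written because the title of the series names those themes. Several lists share genes. Tcf21, for example, stands in the podocyte and the fibroblast list. The design, the lists, the alternatives and the rule for named genes were set before the data were examined. By that rule the text names Abl1, Abl2, Cdh16, Ctnnb1, Pdgfra, Acta2, Col1a1, Fn1 and Vim whatever their result, then up to 12 genes per direction with the largest absolute log2 fold change among genes past the threshold with mean FPKM of at least 1 and no overlap between the groups. Where fewer than 5 passed in a direction, the 5 genes with the smallest p among those that did not pass were added. It also takes 2 to 4 members with the smallest p of each list discussed. Predicted genes were left out.

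The test was tried on simulated data in which 200 of 13390 genes were changed, in 20 simulations of 3 against 3 libraries. With the residual spread of these libraries, limma recovered 65.8% of 2-fold and 96.7% of 4-fold changes, 6.3% of its calls were false, and camera called 0.05 lists per simulation on average. The simulated noise was drawn for each gene on its own. These runs therefore do not show how often either test errs where genes vary together, as they do in the real lists. Both simulated groups also had the same spread for a gene. In the data Col1a1, for example, had a standard deviation of 12.4 FPKM in floxed and 32.4 FPKM in knockout libraries. The recovery given need not hold for such genes.

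Alternatives covered the pseudocount (0.1 and 0.01), the filter (none, and mean FPKM of at least 5), the scaling (TPM, median ratio, quantile), limma without the trend, with robust moderation and with array weights, a replicate block, each library left out in turn, an adjusted p threshold of 0.1, a 2-fold minimum, and the other list tests. Counts per list without knockout replicate 3 were added after the data were seen. The design also foresaw a count-based test in case the table held read counts. The table holds FPKM, so that test was not run.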

Results

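Whole-kidney messenger RNA was measured in 6 libraries from male mice after 14 days of unilateral ureteral obstruction, a model of kidney scarring. There were 3 libraries from control mice and 3 from mice that lost Abl1 in Ksp-Cre-expressing tubule epithelium. The controls, which keep the tyrosine kinase gene Abl1 (c-Abl), are called floxed here after the design text, while their genotype label reads WT. The comparison asks how loss of tubular c-Abl changes gene expression in the obstructed kidney. Unobstructed kidneys were not analysed here, so each value compares 1 obstructed genotype with the other. The spacing of low values implied 16000000 to 17850000 fragments per library. Expression is given as FPKM, with means ± SD over 3 libraries per group. Log2 fold changes are on the log2(FPKM + 1) scale, knockout minus floxed.

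The targeted gene itself, Abl1 (Entrez 11350), was lower in the knockout kidneys. It read 18.16, 15.93 and 17.33 FPKM in floxed replicates 1, 2 and 3 and 10.46, 14.45 and 12.91 FPKM in knockout replicates 1, 2 and 3, so the groups did not overlap. The mean was 17.1 ± 1.13 FPKM in floxed and 12.6 ± 2.01 FPKM in knockout kidneys, 26.4% lower. The log2 fold change of -0.42 (SE 0.144) did not pass the limma test over all genes (adjusted p = 0.144), and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. Ksp-Cre acts in part of the tubule cells, other kidney cells keep Abl1, and a deleted exon need not lower the FPKM of a whole gene, so these values check the labels loosely. Its relative Abl2 read 5.28, 5.56 and 6.04 FPKM in floxed and 3.74, 4.61 and 5.44 FPKM in knockout replicates 1, 2 and 3 (limma adjusted p = 0.335). Cdh16, the cadherin whose promoter drives Ksp-Cre, read 216 ± 17.3 and 321 ± 61.0 FPKM (limma adjusted p = 0.118). The list of Abl kinases and their adaptors did not pass the camera test (adjusted p = 0.143), with 0 of 19 members past the threshold adjusted over the list alone and 18 of 19 below 0. With median-ratio scaling 7 of these members changed sign and the list median went from -0.22 to -0.09. The list passed as lower without knockout replicate 3 (camera adjusted p = 0.0211, 8 lower over the list alone) and with array weights. Dok1, an adaptor phosphorylated by tyrosine kinases, read 19.0 ± 3.31 and 11.5 ± 3.50 FPKM, and the ubiquitin ligase Cbl 8.84 ± 0.520 and 5.96 ± 1.45 FPKM.

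Across the 13390 genes tested, 9 passed the limma threshold, 4 higher and 5 lower in the knockout kidneys. Ifi44l (Entrez 15061), a relative of interferon-induced genes, was near 0 in every floxed library, at 0.09, 0.08 and 0.04 FPKM, and stood at 23.06, 12.05 and 18.28 FPKM in the knockout libraries (log2 fold change 4.09, SE 0.231, limma adjusted p = 0.00635). Cyp4a14 and Cyp4a10, fatty acid omega-hydroxylases and targets of the receptor PPAR-alpha, rose 13.0-fold and 6.18-fold in mean FPKM, from 4.95 ± 2.07 to 64.2 ± 28.8 and from 17.2 ± 1.60 to 106 ± 33.2 FPKM. Lyplal1, a lysophospholipase-like protein, rose 3.40-fold, from 13.7 ± 1.06 to 46.5 ± 10.9 FPKM. Penk, which encodes the opioid precursor proenkephalin, fell from 11.5 ± 3.43 to 1.82 ± 0.242 FPKM. The matrix proteins thrombospondin 2 (Thbs2, 18.1 ± 2.62 to 3.84 ± 1.08 FPKM) and dermatopontin (Dpt, 12.7 ± 1.71 to 2.55 ± 0.748 FPKM) fell as well. So did the cilium transcription factor Foxj1 (10.6 ± 2.06 to 2.48 ± 0.397 FPKM) and the macrophage gene Ms4a7 (27.27, 38.99 and 37.98 against 10.57, 10.6 and 11.93 FPKM). All but Ifi44l had a limma adjusted p of 0.0446, and in each of the 9 the 3 knockout libraries lay outside the range of the 3 floxed libraries. Of the 5 higher genes next in rank, which did not pass (limma adjusted p = 0.0547), the vitamin D receptor Vdr read 23.9 ± 1.87 and 49.7 ± 4.33 FPKM and the acyl-CoA thioesterase Acot1 20.9 ± 1.92 and 44.8 ± 4.51 FPKM. The others were the folate carrier Slc19a1 at 19.3 ± 0.671 and 38.1 ± 3.33, the acyl-CoA synthetase Acsl1 at 21.1 ± 1.10 and 43.7 ± 5.67, and the proton pump subunit Atp6v0a4 at 30.6 ± 0.721 and 66.9 ± 10.6 FPKM.

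The count of 9 lies at the edge of the threshold. At an unadjusted limma p under 0.05 there were 3303 genes, 1122 higher and 2181 lower, and the 2 groups did not overlap for 31.7% of genes, against 10% by chance on average over groupings. Genes vary together, so the share for a single grouping can lie far from that average. Other splits of the 6 libraries into 3 and 3 gave 60 to 1394 genes at that unadjusted limma p. The split with 1394 kept knockout replicates 1 and 2 together, so it held part of the real contrast and does not measure chance alone. With a pseudocount of 0.1 or 0.01, no filter, a mean FPKM of at least 5, median-ratio or quantile scaling, or limma without its trend, the count was 1, Ifi44l. Without floxed replicate 2 or without floxed replicate 3 it was 0, with 2298 and 2146 genes at an unadjusted limma p under 0.05. Without knockout replicate 1 it was 2, without floxed replicate 1 it was 13 and without knockout replicate 2 it was 1. The median log2 fold change of all genes was -0.12, and 34.0% of genes at an unadjusted p under 0.05 were higher. Median-ratio scaling moved that median to 0.0012 and the share to 51.4%, and quantile scaling to -0.0052 and 50.4%. Both scalings bring the libraries to a common centre, so these values follow from the scaling itself. With TPM scaling, which has no such step, the median was -0.18 and the share 31%. Whether more genes fell than rose therefore cannot be told apart from the choice of scaling.

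**Figure D1:**
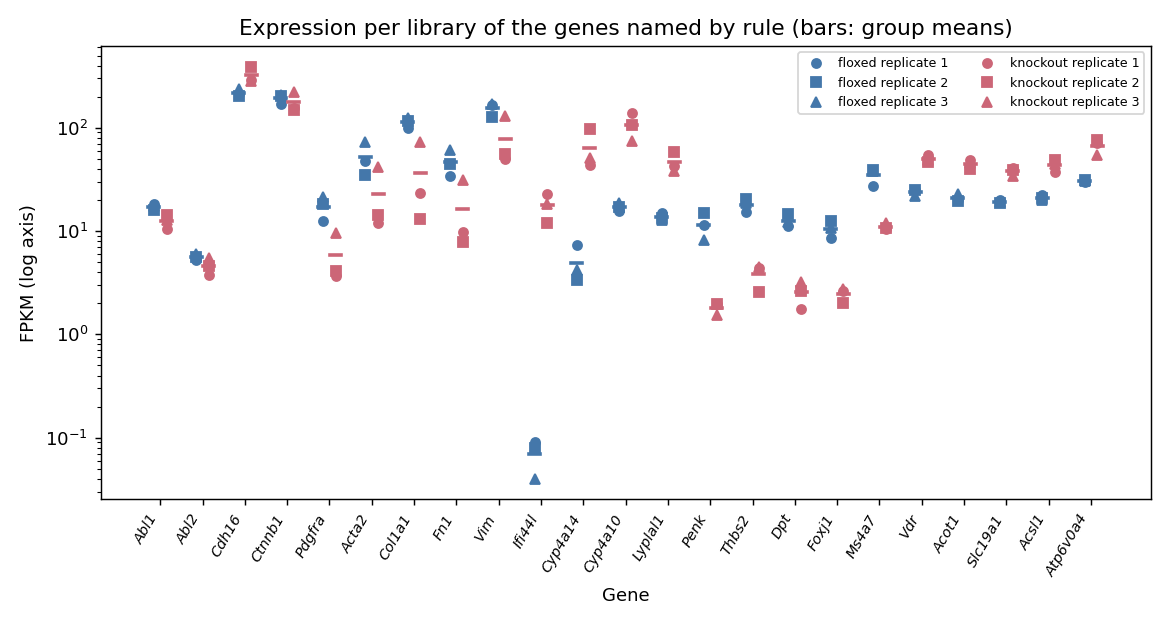
FPKM on a log axis for the genes named by the fixed rule, with a symbol per library (floxed blue, knockout red, shape for the replicate) and a bar for each group mean. Ifi44l stands at 0.04 to 0.09 FPKM in floxed and at 12.05 to 23.06 FPKM in knockout libraries, while Vim, Acta2 and Col1a1 of knockout replicate 3 lie closer to the floxed libraries than those of knockout replicates 1 and 2.

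The 3 knockout libraries were not alike. On the first principal component, which held 61.8% of the variance, the floxed libraries lay at -29.0, -26.2 and -28.8, knockout replicates 1 and 2 at 54.1 and 37.4, and knockout replicate 3 at -7.48. Across genes, knockout replicate 3 had a correlation of 0.968 to 0.969 with the floxed libraries and of 0.941 and 0.960 with knockout replicates 1 and 2, which correlated at 0.977 with each other. Genes are not independent replicates, so these values describe the libraries only. Col1a1 read 23.43 and 13.12 FPKM in knockout replicates 1 and 2 and 73.62 FPKM in replicate 3. Without knockout replicate 3, an alternative planned for every library, 3271 genes passed the limma threshold, 1208 higher and 2063 lower, among them all 9 genes above. The median in each knockout library is therefore given for some of the gene groups, and the plot of list medians shows it for 20 lists. Counts of list members without knockout replicate 3 are given below, and for no other library left out. That library was singled out because it lay toward the floxed libraries, so leaving it out raises the counts by that choice. They show how much rests on 1 library and are no added support.

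**Figure D2:**
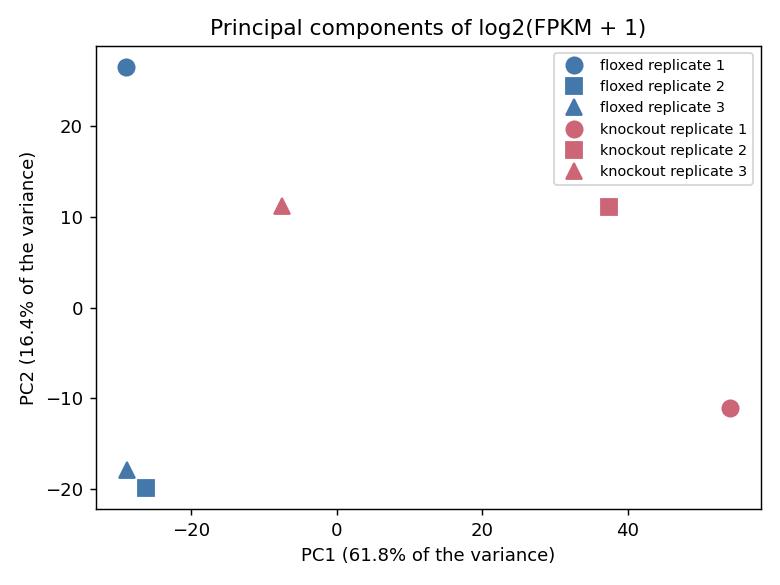
Position of each library on the first and the second principal component of log2(FPKM + 1) over the genes tested (floxed blue, knockout red, shape for the replicate). The floxed libraries lie between -29.0 and -26.2 on the first component, knockout replicates 1 and 2 at 54.1 and 37.4, and knockout replicate 3 at -7.48.

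Of the 45 gene lists tested, 34 passed camera with its preset correlation, 13 higher and 21 lower in the knockout kidneys. None passed with an estimated correlation (lowest adjusted p = 0.484, 2 lists at an unadjusted p under 0.05) or with fry (lowest adjusted p = 0.0691, 16 lists at an unadjusted p under 0.05). Another split of the 6 libraries into 3 and 3 gave up to 33 lists by camera. That split kept knockout replicates 1 and 2 together, so it held part of the real contrast and does not measure chance alone. With none passing under an estimated correlation or fry, a camera call alone is still weak ground for a direction. The counts of members are given beside it. Those counts come from the same comparison and the same genes, which vary together. Adjusting over the list alone also eases the threshold where many members move together. The counts therefore describe these libraries and are not separate support. For 10 of the 34 lists no member passed over the list alone in the direction of the call. Among the 34 lists, 9 lost their camera call in at least 1 other alternative: Wnt ligands and receptors, epithelial junction, endothelial, interferon, hypoxia, erythrocyte, p53, endoplasmic reticulum stress and ribosomal protein genes.

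Genes of fatty acid oxidation rose together. Of 39 members, 33 rose when adjusted over the list alone, 2 when adjusted over all genes, and all 39 were above 0, with a list median of 0.87 (camera adjusted p = 5.16e-30, adjusted p = 0.484 with an estimated correlation). Its leading members are Cyp4a10, Cyp4a14, Acot1 and Acsl1, given above. The median was 1.21, 0.91 and 0.61 above the floxed mean in knockout replicates 1, 2 and 3, and 37 members passed over the list alone without replicate 3. All 43 subunits of oxidative phosphorylation were above 0 with a median of 0.61 (camera adjusted p = 6.02e-19, adjusted p = 0.484 with an estimated correlation), but 0 passed over the list alone with all libraries (16 with TPM scaling) and all 43 without knockout replicate 3. The medians there were 0.89, 0.87 and 0.08 in knockout replicates 1, 2 and 3. Sdhd, a subunit of succinate dehydrogenase, read 88.7 ± 0.785 and 156 ± 28.9 FPKM, and the ATP synthase subunit Atp5a1 315 ± 33.3 and 547 ± 131 FPKM.

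The lists of tubule segment markers passed camera as higher, with few members past the threshold over the list alone outside the proximal tubule. Of 49 proximal tubule genes, 17 rose when adjusted over the list alone and 0 when adjusted over all genes, with a list median of 1.14 (camera adjusted p = 5.14e-19, adjusted p = 0.484 with an estimated correlation). The gluconeogenic enzymes Pck1 and G6pc rose 6.25-fold and 8.13-fold (119 ± 13.2 to 746 ± 415 and 9.80 ± 2.82 to 79.7 ± 47.0 FPKM), the bicarbonate transporter Slc4a4 1.88-fold (49.8 ± 3.78 to 93.6 ± 11.8 FPKM) and the lactate transporter Slc5a12 3.52-fold (19.3 ± 2.12 to 67.8 ± 32.9 FPKM). List medians were 2.02, 1.28 and 0.25 in knockout replicates 1, 2 and 3, and 43 of the 49 genes passed over the list alone without replicate 3. In the thick ascending limb list 3 of 18 rose over the list alone (13 without knockout replicate 3, 10 with median-ratio scaling, 6 higher and 1 lower with TPM scaling), among them the potassium channel Kcnj1 (30.1 ± 5.47 to 67.6 ± 20.6 FPKM). In the distal convoluted and connecting tubule list 4 of 14 rose, among them kallikrein Klk1 (148 ± 47.1 to 716 ± 391 FPKM) and the calcium-binding S100g (65.0 ± 33.1 to 418 ± 312 FPKM), and 9 rose and 1 fell without knockout replicate 3. Principal cells of the collecting duct showed 3 of 17 rising (12 with median-ratio and 5 with quantile scaling, 11 higher and 1 lower without knockout replicate 3), with the water channel Aqp4 at 1.57 ± 0.175 and 6.08 ± 2.38 FPKM and the sodium channel subunit Scnn1a at 15.6 ± 1.51 and 36.3 ± 13.2 FPKM. In the thin limb list 3 of 10 rose (2 with median-ratio scaling) and 4 were below 0, with medians of -0.11, 0.28 and 0.54 in knockout replicates 1, 2 and 3, led by Crym (14.1 ± 1.81 to 24.7 ± 0.318 FPKM). All 17 intercalated cell genes were above 0, yet 0 passed over the list alone (4 with median-ratio and 3 with quantile scaling, 13 without knockout replicate 3). The acid-base genes Aqp6 and Atp6v1b1 there read 12.6 ± 5.28 and 33.7 ± 14.2 FPKM, and 31.1 ± 8.82 and 67.6 ± 29.0 FPKM. These 5 segment lists passed camera as higher with list medians of 0.63, 0.88, 0.87, 0.23 and 0.95 in the order given (adjusted p = 0.484 with an estimated correlation in each).

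Collagens and other matrix genes fell. Of 39 members, 33 fell when adjusted over the list alone and 1, Thbs2, when adjusted over all genes, and all 39 were below 0, with a median of -1.37 (camera adjusted p = 9.41e-14, adjusted p = 0.484 with an estimated correlation). The small proteoglycan decorin (Dcn) read 78.86, 80.98 and 80.24 FPKM in floxed and 26.34, 25.66 and 40.33 FPKM in knockout replicates 1, 2 and 3. Its relative biglycan (Bgn) went from 356 ± 68.8 to 110 ± 47.5 FPKM, and Col15a1 from 49.9 ± 12.1 to 14.4 ± 6.60 FPKM. Col1a1, the main collagen of scar tissue, read 113 ± 12.4 and 36.7 ± 32.4 FPKM (limma adjusted p = 0.109), and fibronectin (Fn1) 46.6 ± 13.4 and 16.3 ± 12.8 FPKM (limma adjusted p = 0.110). List medians were -1.63, -1.78 and -0.65 in knockout replicates 1, 2 and 3. Of 22 genes of matrix turnover, 15 fell over the list alone (camera adjusted p = 2.62e-05, adjusted p = 0.484 with an estimated correlation), such as cathepsin K (Ctsk, 26.4 ± 5.07 to 8.30 ± 3.02 FPKM) and the metalloproteinase Mmp11 (23.6 ± 2.03 to 8.87 ± 3.30 FPKM). The basement membrane list did not pass camera (adjusted p = 0.199, 0 of 20 past the threshold over the list alone, 10 lower and 1 higher without knockout replicate 3, where it passed as lower with a camera adjusted p of 0.0444). Laminin Lama2 read 4.32, 3.59 and 6.76 FPKM in floxed and 1.5, 1.85 and 2.66 FPKM in knockout replicates 1, 2 and 3, and Nid1 stood at 28.5 ± 8.05 and 13.8 ± 7.20 FPKM.

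Fibroblast markers fell as well. Of 21 members, 16 fell when adjusted over the list alone and 1, Dpt, over all genes, with a median of -1.27 (camera adjusted p = 3.21e-07, adjusted p = 0.484 with an estimated correlation). The stromal transcription factor Tcf21 went from 82.2 ± 34.2 to 19.6 ± 2.55 FPKM and Islr from 11.3 ± 2.87 to 3.07 ± 1.26 FPKM. Smooth muscle actin (Acta2), a myofibroblast marker, read 51.8 ± 19.4 and 22.8 ± 16.8 FPKM (limma adjusted p = 0.165), with 42.16 FPKM in knockout replicate 3 within the floxed range. List medians were -1.53, -1.38 and -0.50 in knockout replicates 1, 2 and 3. Among smooth muscle, pericyte and renin cell genes 6 of 18 fell over the list alone (11 without knockout replicate 3 and 3 with quantile scaling), such as the guanylate cyclase subunit Gucy1a1 (21.6 ± 2.62 to 6.06 ± 2.66 FPKM) and desmin (Des, 13.2 ± 1.02 to 4.83 ± 2.80 FPKM). That list passed camera (adjusted p = 0.00495, adjusted p = 0.533 with an estimated correlation). Podocyte genes showed 5 of 15 falling over the list alone (7 with TPM scaling, 1 with median-ratio or quantile scaling), Tcf21, which is also a fibroblast marker, being the strongest, and Ptpro reading 7.92 ± 1.17 and 4.49 ± 0.752 FPKM (camera adjusted p = 0.00119, adjusted p = 0.484 with an estimated correlation). In the endothelial list 1 of 21 fell over the list alone, the TGF-beta co-receptor Eng (36.92, 29.9 and 42.09 FPKM in floxed and 20.49, 17.71 and 21.7 FPKM in knockout replicates 1, 2 and 3), and 0 with median-ratio scaling. Its camera call (adjusted p = 0.0476, adjusted p = 0.710 with an estimated correlation) was lost without knockout replicate 3 (camera adjusted p = 0.189), without floxed replicate 1, floxed replicate 3 or knockout replicate 1 and with TPM scaling, limma without its trend or array weights.

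**Figure D3:**
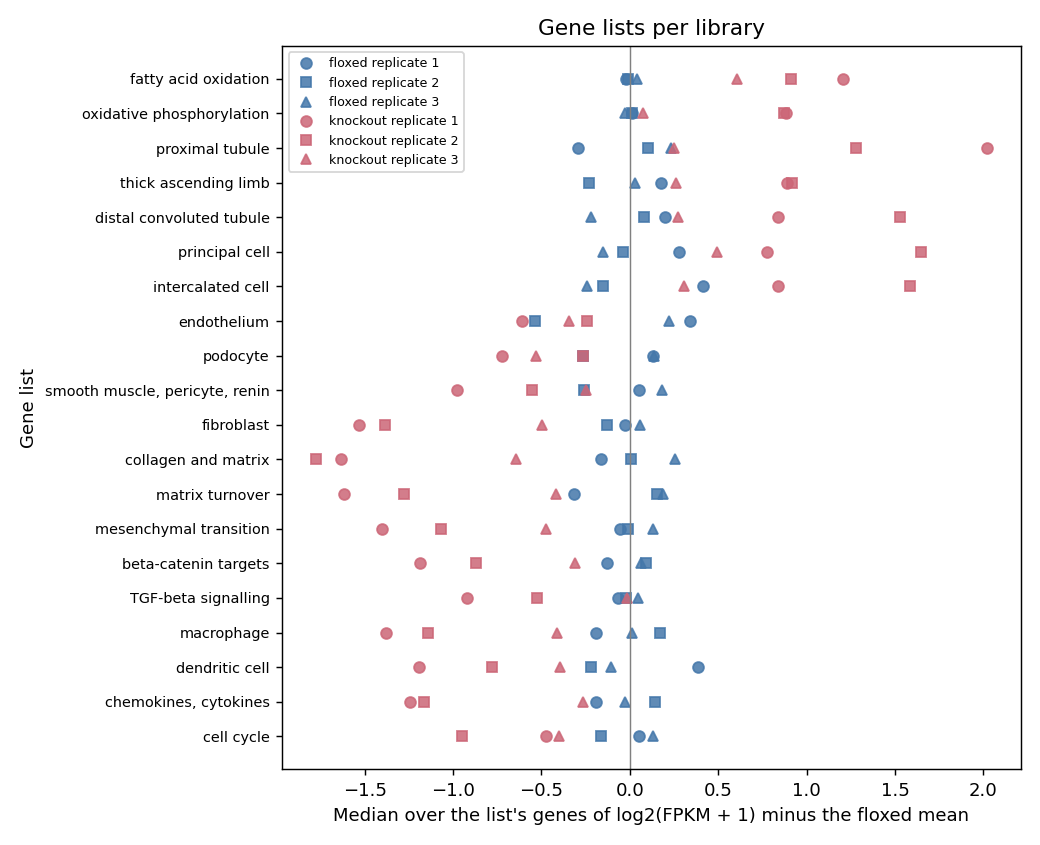
Median over each of 20 gene lists of log2(FPKM + 1) minus the floxed mean of the gene, for each of the 6 libraries (floxed blue, knockout red, shape for the replicate); the vertical line marks 0. The proximal tubule medians are 2.02, 1.28 and 0.25 and the collagen and matrix medians -1.63, -1.78 and -0.65 in knockout replicates 1, 2 and 3.

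The title of the series names mesenchymal transition, Wnt and beta-catenin signalling and PDGFRA-positive tubule cells. Of 21 genes of mesenchymal transition, 16 fell when adjusted over the list alone and 0 over all genes, with a median of -0.85 (camera adjusted p = 1.28e-06, adjusted p = 0.484 with an estimated correlation). The transcription factors Twist1 and Prrx1 went from 4.01 ± 2.12 to 0.597 ± 0.0850 and from 4.21 ± 1.05 to 1.30 ± 0.723 FPKM. Another, Zeb2, read 12.16, 10.73 and 13.09 FPKM in floxed and 5.25, 5.45 and 8.2 FPKM in knockout replicates 1, 2 and 3. Vimentin (Vim), an intermediate filament of mesenchymal cells, read 155 ± 24.0 and 78.2 ± 43.9 FPKM (limma adjusted p = 0.133). Many of these genes are also expressed by fibroblasts, and whole tissue does not show which cells held the transcripts. Epithelial junction genes went both ways, with 0 of 27 past the threshold over the list alone (4 higher with median-ratio scaling, 4 higher and 2 lower without knockout replicate 3). Their camera call as higher (adjusted p = 0.0109, adjusted p = 0.611 with an estimated correlation) had a list median of 0.01, which was -0.04 with TPM scaling and -0.14 without knockout replicate 3. The call was lost there, with quantile scaling and with array weights. Claudin 2 (Cldn2) read 97.57, 118.8 and 118 FPKM in floxed and 171.5, 156.7 and 173.8 FPKM in knockout replicates 1, 2 and 3.

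Transcriptional targets of beta-catenin included 8 of 27 that fell over the list alone and 1 that rose (17 and 2 without knockout replicate 3), with a median of -0.75 (camera adjusted p = 0.0119, adjusted p = 0.484 with an estimated correlation). The Wnt feedback inhibitors Nkd2 and Nkd1 went from 14.4 ± 2.43 to 3.04 ± 1.59 and from 8.95 ± 1.30 to 2.61 ± 1.23 FPKM, and Ccn4 from 4.53 ± 0.311 to 1.67 ± 0.761 FPKM. Transcripts of beta-catenin itself (Ctnnb1) stood at 193 ± 21.6 and 176 ± 40.6 FPKM (log2 fold change -0.15, SE 0.189, limma adjusted p = 0.627), and the list of the core pathway did not pass camera (adjusted p = 0.0793, 0 of 24 past the threshold over the list alone), though it did as lower without knockout replicate 3 (camera adjusted p = 0.0458), with no filter and with a mean FPKM of at least 5. Its member Csnk1e, a casein kinase, read 26.9 ± 2.07 and 16.5 ± 4.89 FPKM, and the co-repressor Tle1 8.24 ± 1.58 and 4.98 ± 1.37 FPKM. Among 32 Wnt ligands, receptors and secreted inhibitors 1 fell over the list alone, the receptor Fzd2 (4.58 ± 0.493 to 2.27 ± 0.304 FPKM), and 7 without knockout replicate 3. None fell with TPM or quantile scaling, and 1 rose with median-ratio or quantile scaling. That list passed camera (adjusted p = 0.0408, adjusted p = 0.669 with an estimated correlation) and lost the call with quantile scaling (camera adjusted p = 0.191), with a mean FPKM of at least 5 and without floxed replicate 3, knockout replicate 1 or knockout replicate 2. In the PDGF list 3 of 6 fell over the list alone (5 without knockout replicate 3, and 1 rose beside the 3 with median-ratio or quantile scaling). These were the receptors Pdgfra (17.2 ± 4.45 to 5.81 ± 3.34 FPKM) and Pdgfrb (32.3 ± 2.84 to 13.7 ± 7.76 FPKM) and the ligand Pdgfb (78.0 ± 25.1 to 36.3 ± 15.8 FPKM). Over all genes Pdgfra had a limma adjusted p of 0.0806, and the list had a camera adjusted p of 0.0870 (0.0211 without knockout replicate 3). The list also passed as lower with array weights and with the replicate block. Of 25 TGF-beta genes, 8 fell and 1 rose over the list alone (18 and 1 without knockout replicate 3), such as Ltbp3 (32.7 ± 3.21 to 18.4 ± 1.82 FPKM) and the feedback inhibitor Pmepa1 (46.5 ± 5.46 to 20.8 ± 5.72 FPKM; camera adjusted p = 0.00341, adjusted p = 0.611 with an estimated correlation).

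Macrophage transcripts were lower in the knockout kidneys. Of 31 macrophage and monocyte genes, 19 fell when adjusted over the list alone and 1, Ms4a7, over all genes, with a median of -0.99 (camera adjusted p = 1.57e-07, adjusted p = 0.484 with an estimated correlation). Aif1 went from 62.0 ± 9.99 to 30.4 ± 3.29 FPKM, the complement component C1qc from 245 ± 30.2 to 110 ± 31.2 FPKM and the macrophage antigen Adgre1 (F4/80) from 22.4 ± 4.74 to 10.6 ± 1.63 FPKM. List medians were -1.38, -1.14 and -0.41 in knockout replicates 1, 2 and 3. Dendritic cell genes showed 9 of 15 falling over the list alone (2 with quantile scaling, 14 without knockout replicate 3), such as Clec9a (4.46 ± 0.413 to 2.16 ± 0.376 FPKM) and the integrin Itgax (17.0 ± 1.31 to 7.62 ± 3.95 FPKM; camera adjusted p = 6.61e-05, adjusted p = 0.484 with an estimated correlation). Complement genes showed 10 of 18 falling, such as properdin (Cfp, 34.4 ± 3.45 to 12.8 ± 2.97 FPKM; camera adjusted p = 0.00296, adjusted p = 0.558 with an estimated correlation). Chemokines and cytokines passed camera as lower (adjusted p = 5.96e-05, adjusted p = 0.484 with an estimated correlation) with 0 of 36 past the threshold over the list alone, 10 with TPM scaling and 25 without knockout replicate 3. Il33, an alarmin, read 27.5 ± 9.22 and 9.06 ± 7.01 FPKM, and the chemokine Cx3cl1 99.4 ± 15.3 and 56.8 ± 16.9 FPKM. NF-kappaB targets likewise had 0 of 24 past the threshold (21 lower and 1 higher without knockout replicate 3; camera adjusted p = 0.00527, adjusted p = 0.641 with an estimated correlation), with Nfkb2 at 42.0 ± 2.34 and 27.2 ± 9.35 FPKM and Ikbke at 12.5 ± 1.71 and 6.67 ± 2.47 FPKM. In the interferon list 1 of 40 fell over the list alone, Oas2 (12.7 ± 0.626 to 5.71 ± 1.55 FPKM; camera adjusted p = 0.0209, adjusted p = 0.710 with an estimated correlation). The list call was lost without floxed replicate 1, without knockout replicate 2 and with array weights.

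Lymphoid, neutrophil and urothelial lists did not pass camera, and no member passed over the list alone. Without knockout replicate 3, 5 of 15 urothelial and 1 of 20 T and NK cell genes fell over the list alone. The T and NK cell list (20 members, camera adjusted p = 0.272) included Cd4 at 8.15 ± 5.14 and 2.38 ± 0.356 FPKM, and passed as lower without floxed replicate 2 or 3. The B and plasma cell list (9 members, camera adjusted p = 0.312) was uneven among floxed kidneys and passed as higher without floxed replicate 1. Jchain, which joins secreted antibodies, read 3567, 13.19 and 8.02 FPKM in floxed replicates 1, 2 and 3 and 299.3, 1077 and 757.1 FPKM in knockout replicates 1, 2 and 3. Neutrophil and mast cell genes (10 members, camera adjusted p = 0.489) included Il1b at 19.8 ± 13.6 and 5.17 ± 3.67 FPKM, and urothelial genes (15 members, camera adjusted p = 0.483) Upk2 at 6.39 ± 4.36 and 2.92 ± 1.85 FPKM.

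The cell cycle and immediate early lists passed camera as lower, with counts of members that differed between scalings for the former. Of 41 cell cycle genes, 27 fell when adjusted over the list alone with FPKM as deposited and 0 with median-ratio or quantile scaling, while all 41 were below 0 with FPKM as deposited and the median was -0.61 (camera adjusted p = 2.15e-08, adjusted p = 0.484 with an estimated correlation). The replication factor Mcm3 went from 11.4 ± 1.67 to 6.77 ± 1.15 FPKM and the mitotic kinase Aurkb from 4.12 ± 0.574 to 1.70 ± 0.868 FPKM. Of 23 immediate early genes, which rise with handling as well as with signalling, 7 fell over the list alone (16 without knockout replicate 3), such as Egr2 (13.0 ± 4.30 to 2.76 ± 1.53 FPKM) and Nr4a1 (13.5 ± 3.81 to 3.64 ± 1.16 FPKM; camera adjusted p = 0.000118, adjusted p = 0.558 with an estimated correlation). The p53, apoptosis and senescence list (camera adjusted p = 0.0167, adjusted p = 0.641 with an estimated correlation) and the endoplasmic reticulum stress list (camera adjusted p = 0.0275, adjusted p = 0.669 with an estimated correlation) were lower as lists with 0 of 32 and 0 of 22 members past the threshold over the list alone, against 18 lower and 1 higher and 8 lower without knockout replicate 3. Both calls were lost without floxed replicate 2, the former also without knockout replicate 2 and the latter also without floxed replicate 3 or knockout replicate 1. Plk2 read 16.1 ± 3.52 and 6.57 ± 2.86 FPKM and the chaperone Hsp90b1 348 ± 37.8 and 240 ± 36.3 FPKM. Injured tubule genes did not pass camera (adjusted p = 0.123) with 0 of 31 past the threshold over the list alone. They passed as lower without knockout replicate 3 (camera adjusted p = 0.000275, 16 lower and 1 higher) and without floxed replicate 1. With all libraries kept they passed as lower with median-ratio scaling, quantile scaling, array weights and the replicate block. They did not pass with TPM scaling (camera adjusted p = 0.131), so this call depends on the processing. Dcdc2a there read 60.2 ± 9.85 and 36.4 ± 9.94 FPKM and the tissue inhibitor Timp2 68.2 ± 14.2 and 34.5 ± 17.1 FPKM.

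The list of antioxidant genes under Nrf2 passed camera as higher, with 4 of 23 rising over the list alone (10 without knockout replicate 3, 7 with quantile scaling; camera adjusted p = 1.74e-07, adjusted p = 0.484 with an estimated correlation). The glutathione transferase Gsta2 went from 90.9 ± 34.1 to 363 ± 85.2 FPKM and Nqo1 from 10.1 ± 0.665 to 31.9 ± 11.6 FPKM. Glycolysis passed camera as higher (adjusted p = 0.00119, adjusted p = 0.484 with an estimated correlation), with a median of 0.35, and 10 members rose and 3 fell over the list alone without knockout replicate 3. With all libraries 1 of 21 passed over the list alone (0 with quantile scaling, 1 lower and 1 higher with median-ratio scaling), Hk3, a hexokinase of myeloid cells, which went from 4.91 ± 1.02 to 1.98 ± 0.497 FPKM. Pgk1 read 171 ± 6.93 and 274 ± 53.6 FPKM. In the hypoxia list 1 of 20 rose over the list alone (5 with median-ratio and 2 with quantile scaling, 2 higher and 1 lower without knockout replicate 3), Bnip3 (53.9 ± 1.55 to 100 ± 20.2 FPKM), and its median was 0.07 (camera adjusted p = 0.0275, adjusted p = 0.484 with an estimated correlation). The call was lost with a mean FPKM of at least 5, quantile scaling and array weights, and without floxed replicate 1 or knockout replicate 2. The erythrocyte call was lost under the same alternatives and with median-ratio scaling. Erythrocyte genes had a median of 0.25 with 0 of 9 past the threshold over the list alone (2 higher without knockout replicate 3, 1 higher with quantile scaling; camera adjusted p = 0.0196, adjusted p = 0.484 with an estimated correlation). Their median was 0.08 without knockout replicate 3, and -0.21, 1.015 and 0.40 in knockout replicates 1, 2 and 3. Fech, which makes heme, read 21.6 ± 1.01 and 32.2 ± 5.23 FPKM. Ribosomal protein genes had a median of -0.18, which was -0.04 with median-ratio scaling, where 10 of 43 members changed sign. The call was lost there, with no filter, with array weights and without floxed replicate 1 or 2 or knockout replicate 1 or 2, and 0 of 43 passed over the list alone (camera adjusted p = 0.0491, adjusted p = 0.741 with an estimated correlation). The nephron development list did not pass camera (adjusted p = 0.282), although 3 of 18 fell over the list alone (7 without knockout replicate 3), among them Hoxa11 (6.07 ± 0.981 to 2.15 ± 0.860 FPKM) and Hoxd11 (3.51 ± 0.136 to 1.30 ± 0.626 FPKM), and 1 rose, Bmp7 (6.26 ± 0.632 to 12.3 ± 3.38 FPKM). Adipocyte genes did not pass either (8 members, camera adjusted p = 0.171), with the desaturase Scd1 rising and the transporter Slc36a2 falling over the list alone. Adrenal and skeletal muscle lists had 2 and 3 tested members and mitochondrially encoded genes none in the table, so these were not tested.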

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

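The alternatives here were planned before the data were examined, apart from the per-list counts without knockout replicate 3. Abl1 kept its direction and stayed short of the threshold in every alternative, with a log2 fold change of -0.52 to -0.31 over the libraries left out in turn and of -0.49 to -0.29 in the others, and limma adjusted p between 0.0908 and 0.332. The number of genes past the threshold was 9 with the design as planned. It was 1 with a pseudocount of 0.1 or 0.01, without the filter, with a mean FPKM of at least 5, with median-ratio scaling, with quantile normalisation and with limma without the trend. It was 10 with TPM, 9 with robust moderation or a 2-fold minimum, 997 at a threshold of 0.1 and 1456 with array weights, whose fit stopped before convergence. Leaving out each library in turn gave 0 to 3271 genes, the latter without knockout replicate 3. The cause of these shifts was not tested. Lists past camera numbered 28 to 37 in the other alternatives, against 34, but 0 with camera with estimated correlation and 0 with fry. Robust moderation gives no list value, since camera has no such option. None of the genes in the plot of genes named by the fixed rule reversed. Members of several lists did change sign with another scaling. There were 4 lists, none past the threshold in the design as planned, whose camera direction reversed, not always with the sign of the median. These were B and plasma cells without the filter (median -0.19), and T and NK cells with array weights (-0.17) and without floxed replicate 1 (0.0091). Neutrophil and mast cell genes reversed without floxed replicate 2 (-0.04) or knockout replicate 1 (0.15), and urothelial genes without floxed replicate 3 (-0.30) or knockout replicate 1 (-0.14). Over the libraries left out in turn these medians ranged from -0.79 to 0.0091, from -1.30 to 0.15 and from -1.21 to -0.14 for T and NK, neutrophil and urothelial genes. With the replicate block, 2 genes passed, Ifi44l and Cyp2a5, which is not among the 9. Abl1 then had a log2 fold change of -0.42 (limma adjusted p = 0.247) and 35 lists passed, with the PDGF and injured tubule lists gained as lower and the ribosomal protein list lost. Same-numbered libraries deviated from their group means with correlations of -0.126, -0.0699 and 0.034, and differently numbered ones with -0.122 to 0.135. These values show no pairing by number, and not every library correlated best with its own number. With 3 libraries per group they cannot exclude a shared litter, day or batch. No read totals are in the table, so how depth limits low genes rests on the estimate from the spacing of values.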

Other observations

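Outside the fixed lists, and chosen after their values were seen, 8 of the genes with the widest gap between the groups are given here, and no theme among such genes was tested. Higher in all 3 knockout kidneys were the drug-metabolising Cyp2a5 (23.58, 15.25 and 8.64 FPKM in floxed, 381.7, 168.1 and 82.83 FPKM in knockout replicates 1, 2 and 3), the tyrosine-degrading Hpd (1.6, 1.9 and 0.5 against 37.52, 54.06 and 6.67 FPKM), the fructose transporter Slc2a5 (5.33, 4.16 and 6.24 against 29.68, 22.0 and 13.97 FPKM) and Vnn1 (8.58, 11.74 and 11.62 against 56.88, 27.39 and 35.27 FPKM). Lower in all 3 were the natriuretic peptide receptor Npr3 (6.41, 13.12 and 11.81 against 1.78, 2.49 and 1.61 FPKM), pleiotrophin (Ptn, 13.69, 14.7 and 28.41 against 4.42, 5.07 and 3.67 FPKM), matrix Gla protein (Mgp, 1431, 2099 and 1992 against 417.8, 349.3 and 694.7 FPKM) and the lysozyme Lyz1 (110.5, 119.0 and 123.3 against 30.78, 38.36 and 54.99 FPKM). These genes did not pass the limma threshold (adjusted p between 0.0547 and 0.0652), and all 8 passed it without knockout replicate 3 (limma adjusted p between 0.00294 and 0.0141).

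The tests in this part on the count of genes, tubule share, cortex, the gap between tubule and matrix lists and Ifi44l were chosen after the results were seen; those on the count of lists, the label and mixture of knockout replicate 3, the share of lists kept under other scalings and the motile cilium genes were written before. For the group comparison itself, 1 of the 10 splits of the 6 libraries, the real one, gave as many as 9 genes, and the highest of the others gave 0. For lists that was again 1 of 10, with 34 lists against a highest other of 33. With 10 splits the share cannot fall under 0.05. Bootstrap intervals below resample genes, so they leave out the spread between libraries.

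A first pattern is knockout replicate 3, which lies between the other knockout kidneys and the floxed kidneys. A floxed mouse under a wrong label, with a kidney like the other floxed ones, is argued against. The 1000 genes that best separated knockout replicates 1 and 2 from 2 floxed libraries were used. Replicate 3 lay past halfway to the knockout level for at least 25.7% of them, and a held-out floxed library for at most 8.2%. A floxed kidney with a milder obstruction could also lie past halfway, so these shares do not exclude it. Ifi44l, a single gene, stood at 18.28 FPKM in knockout replicate 3. A mixture of RNA from a knockout and a floxed kidney like the others is argued against too, since its position was 0.437 higher in the fibroblast list than in the proximal tubule list (95% bootstrap interval 0.249 to 0.643, with 0 the floxed and 1 the knockout level). That holds only for kidneys near the group means, since the interval takes in no spread between kidneys. Abl1 read 12.91 FPKM in it, between 10.46 and 14.45 FPKM in knockout replicates 1 and 2, so its values do not point to a milder recombination, although whole tissue measures that loosely. Another course of the obstruction or a difference in dissection may give such a library, and neither was tested.

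The second pattern is that camera called tubule lists higher and fibroblast and macrophage lists lower. A larger share of tubule cells alone would dilute the other cell types alike. The fibroblast list fell further than the endothelial list by a median log2 of -0.919 (95% bootstrap interval -1.06 to -0.459). Podocyte and T and NK cell medians (-0.585 and -0.52) lay closer to the endothelial median (-0.35) than to the fibroblast median. In knockout replicates 1, 2 and 3 fibroblast medians were -1.53, -1.38 and -0.50 and endothelial medians -0.61, -0.24 and -0.34. The gap was wider than in any floxed library in replicates 1 and 2 but not in 3, so the test does not decide for the 3 together. More cortex and less medulla in the knockout samples would raise podocyte genes, whose median was -0.585, and lower collecting duct genes, whose median was 0.87. A larger tubule share would itself lower podocyte genes, and the podocyte median was -0.267 in both knockout replicate 2 and floxed replicate 2. The podocyte value therefore cannot argue against more cortex. Collecting duct medians were 0.77, 1.65 and 0.49 in knockout replicates 1, 2 and 3 and at most 0.28 in floxed libraries. These go against less medulla alone. The FPKM denominator multiplies a library by 1 factor, so it cannot part the proximal tubule from the matrix list, yet their medians lay 2.53 apart with median-ratio scaling (95% bootstrap interval 2.25 to 2.65). In knockout replicate 3 alone these 2 medians were 0.25 and -0.65 with FPKM as deposited. The share of lists kept under other scalings, at least 88.2%, is left out of this argument, because camera compares a list with other genes, which the same factor moves too, and some list calls did change with the scaling. No test here tells an effect of the knockout from a milder obstruction in some kidneys or from chance, so the cause stays open.

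The third pattern is Ifi44l, the single gene of 18849 that stayed below 0.5 FPKM in every library of 1 group and above 5 FPKM in every library of the other. A general interferon response is argued against by the interferon list, whose median was -0.349. Reads moved from its neighbour and relative Ifi44 are argued against too: Ifi44 changed by 2.07 FPKM (95% interval -3.21 to 7.36), where a loss as large as the gain of 17.7 FPKM in Ifi44l would be needed. A stretch of another strain's genome carried by the knockout line is a candidate explanation that stays open. That 0 of the 40 neighbouring genes were on in 1 group only does not bear on it. Ifi44l was the only such gene of all, which fixed that count, and neighbours need not carry such a variant.

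Lower Foxj1 may go with less of the motile cilium programme that it controls. Of 42 motile cilium genes written down before their values were seen, 13 were expressed enough to test, their median log2 fold change was -0.194 (95% bootstrap interval -0.522 to 0.00864) and 0 passed the limma threshold, with 3 at an unadjusted p under 0.05, so the test does not decide.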
